A study of Mus musculus with 7 samples.

How the data were processed

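RNA was taken from the extensor digitorum longus muscles of 4 wild type and 3 AMPK α1α2 double knockout mice, extracted with TRIzol, and 100 ng of total RNA per sample was labelled with biotin using the Ambion WT Expression Kit, per the labels' protocols. The series design counts mice, so each array was taken as 1 mouse. The submitters supplied 1 value table with values of 28856 probe sets on the 7 arrays. Background correction, normalization and summarization software, and the genome build of the array design, are not given in the sources used here. The deposited values were read as log2 expression, since they ran from 4.41 to 14.65 and exceeded the 11.09 that a 16-bit scanner can reach on a natural log scale. The base of the logarithm is therefore inferred, and every log2 difference and fold rests on it. Array medians were 7.52, 7.55, 7.50 and 7.54 in wild type and 7.52, 7.52 and 7.58 in knockout replicates 1 to 3, and quartiles were close but not identical. Whether the arrays had been scaled to each other is not given, and any such scaling would remove a shift shared by all genes. Signal of dim probe sets can be compressed towards background. The number of columns left unused was 0.

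Probe sets were named through the platform annotation supplied by GEO, with symbols checked through gene identifiers against the RefSeq gene table of mouse assembly GRCm38.p6. Of the 28856 probe sets, 21789 had exactly 1 gene symbol and were tested, 1621 had several symbols and 5446 were unnamed here, and neither of these kinds was given a gene name. Of the tested probe sets 21698 matched the RefSeq table, and 0 symbols needed an update. No coordinates were used beyond gene order and distance around the targeted genes in that assembly. The 21789 probe sets stood for 19939 genes, and the 998 genes with several probe sets were counted through the one with the highest mean over all 7 arrays. Named genes with several probe sets went the same way in each, except Hibadh, whose dim second probe set differed by 0.09.

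The comparison was knockout minus wild type over all 7 arrays with no covariate. Differences and standard errors came from limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05 on the adjusted p. Values joined to a gene by ± are the difference and its moderated standard error unless marked SD. No filter on dim probe sets and no array weights were used. The 33 pathway and 13 cell type lists, the named-gene rule, the design and the alternatives were written before the data were examined. The lists hold 801 entries, of which 737 were measured by a probe set with 1 symbol. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted within pathway lists and within cell type lists. The value of a list is the mean over its members, and its standard error comes from the spread of that mean between arrays (n = 4 and n = 3). Camera with an estimated correlation and fry, which asks whether the members move one way on balance without comparing them with other genes, were run beside it. Members were also adjusted over the list alone.

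The rule named the 7 AMPK subunits, and in each direction up to 10 genes of largest change among those with an adjusted p under 0.05 and no overlap, filled to 5 by the smallest p. It also named the 2 members of each pathway list with the smallest p (4 where the list was called), 4 members of called and 1 of other cell type lists, and the most changed gene among 20 neighbours on each side of Prkaa1 and of Prkaa2. It gave 140 entries of genes, and predicted genes passed over numbered 0. Genes named after their values were seen are marked so where they appear.

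The method was tested on simulated data made from these arrays, in 5 runs of 200 changed probe sets each among 21789. A change of 0.5 log2 units was recovered for 73.7% of changed probe sets, 1 unit for 95.3% and 2 units for 100%, with 40 false among 973 calls. A shift of 0.2 put into 2 gene lists in each of the 5 runs was called in 10 of 10 cases, and 1 of 210 unshifted cases was called. The simulated noise was independent between genes, while members of real lists can vary together (estimated correlation 0.82 for immediate early genes). The list rates of the simulation therefore do not carry over to the real lists. The gene rates hold for 200 changed probe sets per run, which makes the adjusted threshold easier to reach than in the real arrays, where 5 genes passed. There Ncam1, at 1.01 ± 0.14, and Atf3, at 2.09 ± 0.61, did not pass. The gene rates therefore do not carry over either, and real changes of 1 unit or more can be missed. The alternatives were the replicate number as a block, quantile normalization, median centring, a filter on dim probe sets, array weights, a trended robust prior, all probe sets, other thresholds, other list tests, the mean of all probe sets of a gene, and leaving out each array in turn. All 35 ways of choosing 3 of the 7 arrays were also fitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.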

Results

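Gene expression was measured in the extensor digitorum longus, a fast-twitch muscle of the mouse hindlimb, with 1 single-colour array per mouse. There were 4 wild type mice and 3 mice labelled as double knockouts of the catalytic subunits α1 and α2 of AMP-activated protein kinase (AMPK), a kinase that is switched on when cellular energy runs low. All mice were of a mixed C57/Bl6 and SV129 background. The title of the series concerns the role of AMPK in muscle use of fatty acids during exercise, so the comparison asks how muscle transcripts differ between these genotypes. The labels do not say whether these muscles had been exercised, whether the deletion was limited to muscle, or what sex the mice were. Log2 values of 19939 genes were compared, and the number of arrays limits the precision of every difference. Array medians lay between 7.501 and 7.584, and Pearson's r across genes, which are not independent replicates, ran from 0.9914 to 0.9935 between knockout arrays and from 0.9947 to 0.9975 between wild type arrays. Between the genotypes r ran from 0.9898 to 0.9967. Knockout replicate 1 was closer to the wild type arrays (0.9944 to 0.9967) than to knockout replicates 2 and 3 (0.9933 and 0.9935).

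The knockout arrays were less alike than the wild type arrays. On the first principal component, which held 38.6% of the variance, knockout replicates 2 and 3 lay at 20.3 and 13.5, knockout replicate 1 at -0.757 and the wild type arrays between -11.4 and -5.04. On the second, knockout replicate 3 lay at -18.4 and the other arrays between -2.24 and 13.7. Knockout replicate 3 also had the lowest array weight in limma, 0.294 against 0.765 to 1.99 in the other arrays. Knockout replicate 2 held 72 genes more than 1 log2 unit above all other arrays, against at most 3 in any other array. Among them were 13 of the 22 measured immediate early genes, which are induced within minutes of a stimulus. Fos, named after its values were seen, stood at 11.70 in that array and between 7.56 and 8.17 in the other 6.

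The targeted genes were read first. Prkaa1, which encodes the α1 subunit (probe set 10422707), averaged 9.54 ± 0.06 (SD, n = 4) in wild type and 9.03 ± 0.20 (SD, n = 3) in knockout muscle. This was a log2 difference of -0.51 ± 0.09 (SE), or 1.43-fold lower, and all 3 knockout arrays lay below all 4 wild type arrays. Prkaa2, which encodes the α2 subunit (probe set 10514779), averaged 12.22 ± 0.13 (SD, n = 4) and 12.01 ± 0.05 (SD, n = 3), a log2 difference of -0.21 ± 0.07 (SE). Wild type replicate 2 read 12.03 for Prkaa2, inside the knockout range of 11.95 to 12.04. With limma and Benjamini-Hochberg adjustment over all tested probe sets, the adjusted p was 0.12 for Prkaa1 and 0.39 for Prkaa2, so neither passed. Over the list of 7 AMPK subunits alone, Prkaa1 passed (adjusted p = 0.0050) and Prkaa2 did not (adjusted p = 0.051). The probe sets read sequence along the whole transcript, and which exons were deleted is not given in the sources used here. Probes outside a deleted part do not fall with it, so these values neither establish nor exclude the loss of both subunits, and the genotypes were taken from the labels.

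The remaining subunits are the scaffold β and the nucleotide-binding γ subunits. Prkab2 differed by -0.21 ± 0.08 and Prkag1 by -0.21 ± 0.07, and for Prkag1 all knockout arrays lay below all wild type arrays. Prkag2 differed by 0.23 ± 0.09 and Prkag3, the γ form typical of fast muscle, by 0.16 ± 0.14. Leaving out 1 array moved several of these: Prkab2 was -0.12 without knockout replicate 3, and without knockout replicate 2 Prkag1 was -0.13 and Prkag2 0.12. Prkag3 was 0.07 without wild type replicate 2, 0.10 without knockout replicate 1, 0.29 without replicate 2 and 0.09 without replicate 3. Prkab1 differed by 0.01 ± 0.05, with a sign that turned to -0.04 under array weights. Of the 7 subunits, 1 fell when p was adjusted over the list alone and 0 when it was adjusted over all genes. The list as a whole was not called (camera adjusted p = 0.099, and adjusted p = 0.28 with an estimated correlation). It was called lower without wild type replicate 2 (camera adjusted p = 0.025) and under array weights (camera adjusted p = 0.039), and its mean ran from -0.133 to -0.0967 when 1 array was left out.

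**Figure D1:**
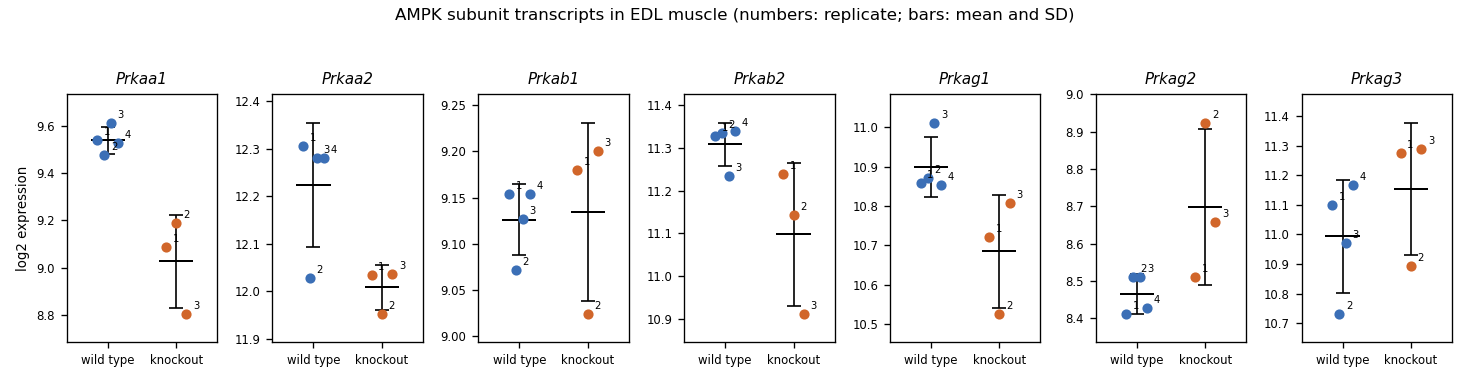
Log2 expression of the 7 AMPK subunit transcripts, 1 panel per gene, with each array as a point numbered by its replicate and the group mean and SD as bars (wild type n = 4, knockout n = 3). Prkaa1 values do not overlap between the genotypes, while wild type replicate 2 lies among the knockout arrays for Prkaa2.

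Myeloid cell transcripts and an embryonic myosin were higher in knockout muscle, and a methyltransferase-like transcript was lower. Lyz2, the lysozyme of macrophages and other myeloid cells (probe set 10372648), rose from 10.58 ± 0.06 (SD, n = 4) to 11.52 ± 0.08 (SD, n = 3), a log2 difference of 0.94 ± 0.05 (SE) or 1.91-fold. Tyrobp, a signalling adaptor of myeloid receptors, rose by 0.63 ± 0.05 (1.55-fold), and Cd300ld, a myeloid surface receptor, by 0.43 ± 0.03 (1.35-fold). Myh3, the embryonic myosin heavy chain that reappears in regenerating fibres, rose by 0.66 ± 0.05 (1.58-fold). Mettl11b, a predicted N-terminal methyltransferase, fell by 1.16 ± 0.10 on the log2 scale, from 9.37 to 8.21 (2.24-fold lower).

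In limma with Benjamini-Hochberg adjustment, these 5 genes, 4 higher and 1 lower, were the only ones of 19939 with an adjusted p under 0.05. The adjusted p was 0.0088 for Lyz2, 0.017 for Tyrobp and Cd300ld, 0.022 for Myh3 and 0.033 for Mettl11b, and each differed in the same direction in all 3 knockout arrays against all 4 wild type arrays. At an adjusted p under 0.10 there were 72 genes, 48 higher and 24 lower. At an unadjusted p under 0.05 there were 2118 genes, 10.6% of those tested with 784 higher and 1334 lower, but another grouping of the 7 arrays into 4 and 3 gave 2334. It set wild type replicates 2 and 4 and knockout replicate 3 apart. Those arrays had the highest medians (7.545, 7.537 and 7.584) and the lowest upper quartiles (8.826, 8.823 and 8.802). Whether that grouping reflects array scaling was not tested. The genotypes did not overlap for 1717 genes, or 8.61%, where chance gives 5.71%. The rule filled each direction to 5 by the smallest p, with genes that did not pass. The higher one was Ctss, the lysosomal protease cathepsin S, at 0.85 ± 0.09. The lower ones were the mitochondrial Cox5a at -0.31 ± 0.04, Sdhc at -0.27 ± 0.03 and Sod2 at -0.31 ± 0.03, and Phyh at -0.47 ± 0.05. Phyh is a peroxisomal enzyme that breaks down branched fatty acids. All these had an adjusted p of 0.083 in limma, and in order of p over both directions further higher genes lay between them. The count of 5 genes became 0 without wild type replicate 1, 3 or 4, 1 without wild type replicate 2, 2 without knockout replicate 2 and 14 without knockout replicate 1. After a further quantile normalization 4 genes were higher and 2 lower.

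**Figure D2:**
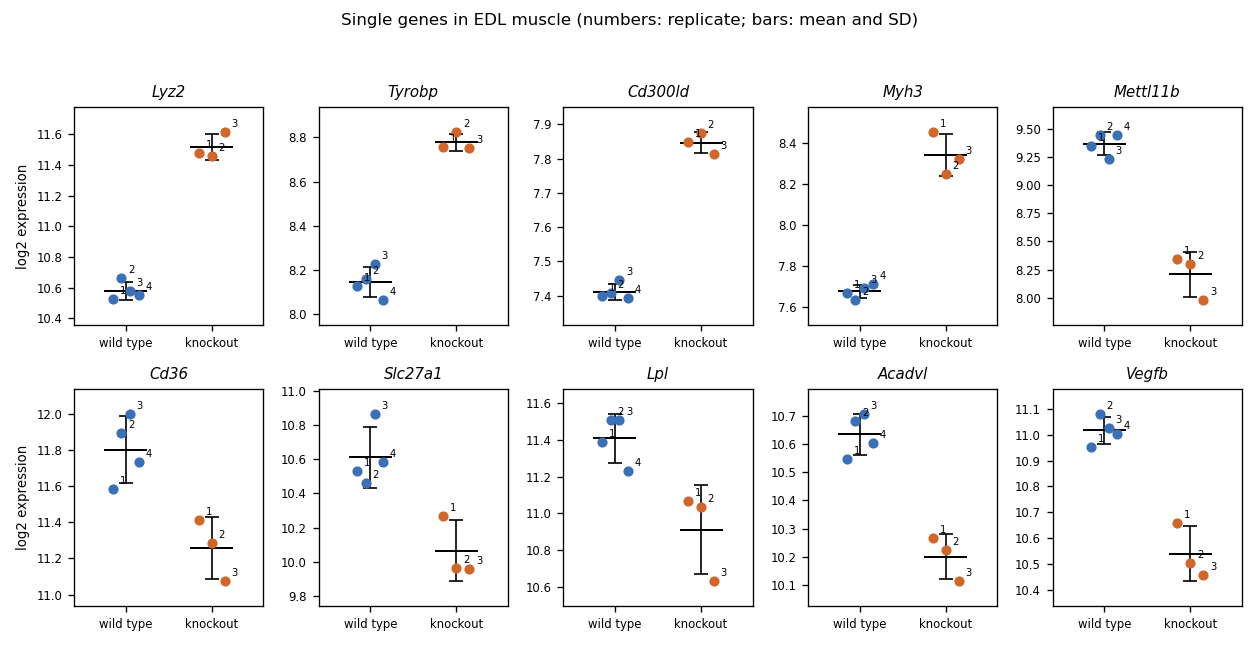
Log2 expression of 10 transcripts, 1 panel per gene, with each array as a point numbered by its replicate and the group mean and SD as bars (wild type n = 4, knockout n = 3). Lyz2, Tyrobp, Cd300ld, Myh3 and Mettl11b passed the test over all genes, and the remaining 5 did not, although no knockout array of any of the 10 lies within its wild type range.

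Gene lists for muscle metabolism, structure and stress were tested as groups. Of 33 pathway lists, 21 were called by camera with a preset correlation of 0.01, with 7 higher and 14 lower in the knockout (7 and 9 after a further quantile normalization). The lists that were lower were led by mitochondrial and fatty acid genes, and those that were higher by immediate early genes, which rested on 1 array, and by regeneration and slow fibre genes. With a correlation estimated from these arrays, 2 of the 21 calls held, the lower tricarboxylic acid cycle list and the higher muscle regeneration list. Other groupings of the 7 arrays into 4 and 3 gave up to 23 called pathway lists with the preset correlation and 0 with the estimated one. The grouping with 23 moved only wild type replicate 2 to the knockout side.

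**Figure D3:**
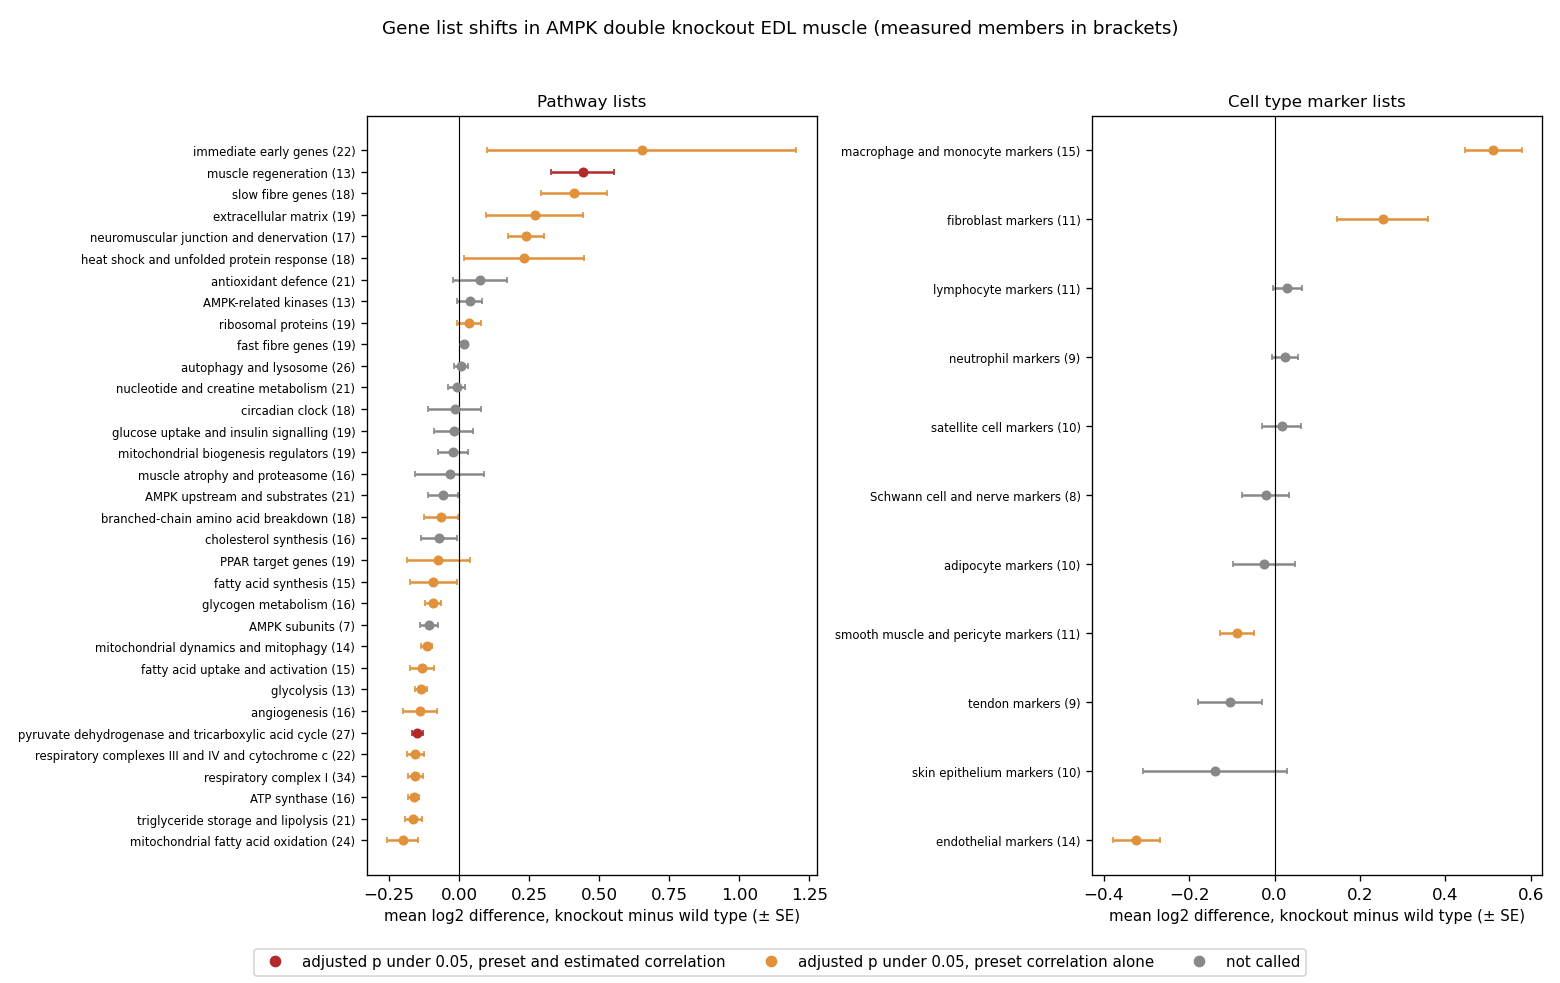
Mean log2 difference of each tested gene list, knockout minus wild type, with the standard error over arrays as bars (wild type n = 4, knockout n = 3) and the number of measured members in brackets. Mitochondrial lists other than the biogenesis regulators (-0.02) lie between -0.20 and -0.12, endothelial markers at -0.32 and macrophage markers at 0.51, and colours separate the calls that hold with an estimated correlation from those that do not.

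Genes that burn fatty acids in mitochondria were lower in knockout muscle. The 24 measured genes of mitochondrial fatty acid oxidation fell by 0.20 ± 0.05 on average, and 16 of them fell when p was adjusted over the list alone, against 0 over all genes. Acadvl, the very long-chain acyl-CoA dehydrogenase that starts each cycle on long chains, differed by -0.43 ± 0.05. Eci1, an isomerase for unsaturated fatty acids, differed by -0.35 ± 0.06, Hadha, the trifunctional protein subunit, by -0.20 ± 0.04, and Crat, carnitine acetyltransferase, by -0.19 ± 0.04. The call rested on a camera adjusted p of 7.8e-13 and was lost with the estimated correlation (adjusted p = 0.12).

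Genes of fatty acid uptake and activation went both ways, with 9 of 15 below and 6 above wild type. When p was adjusted over the list alone 5 fell and 1 rose, and 0 passed over all genes. The fatty acid transporter Slc27a1 and the scavenger receptor and fatty acid translocase Cd36 both differed by -0.54 ± 0.12. Lpl, the lipase that frees fatty acids from circulating triglyceride, differed by -0.50 ± 0.12, and Got2, a mitochondrial aminotransferase also described as a plasma membrane fatty acid-binding protein, by -0.17 ± 0.04. The remaining members that passed over the list alone, named after their values were seen, were the caveolins Cav1 at -0.20 ± 0.07 and Cav3 at 0.23 ± 0.06. The list mean was -0.13 ± 0.04 (camera adjusted p = 0.046, and adjusted p = 0.48 with an estimated correlation), and the call held in 4 of 16 alternatives, being lost among others without wild type replicate 2 or 3 or any 1 of the knockout replicates. Capillary cells express Cd36 as well as muscle fibres do, and the endothelial marker list was lower by 0.32 in the same arrays.

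Triglyceride storage and lipolysis genes fell by 0.16 ± 0.03 on average over 21 members (camera adjusted p = 4.2e-04, and adjusted p = 0.079 with an estimated correlation). Of these, 1 fell over the list alone and 0 over all genes, namely Abhd5, the activator of adipose triglyceride lipase, at -0.24 ± 0.04. The lipase itself, Pnpla2, differed by -0.12 ± 0.04, its inhibitor G0s2 by -0.32 ± 0.11 and the carboxylesterase Ces1f by -0.20 ± 0.07. PPAR target genes averaged -0.07 ± 0.11 over 19 members, with 4 lower over the list alone (Hadha, Cd36, Lpl and Acadl, the last at -0.38 ± 0.10, or -0.24 without knockout replicate 3) and 0 over all genes. That call (camera adjusted p = 0.023) was lost with the estimated correlation (adjusted p = 0.48), and without wild type replicate 2 or 3 or knockout replicate 3. Its mean was -0.034, -0.024 and -0.00092 in those fits, -0.145 without wild type replicate 1, -0.13 without knockout replicate 2 and 0.02 under array weights. Fatty acid synthesis averaged -0.09 ± 0.08 over 15 members, with 0 passing over the list alone or over all genes (camera adjusted p = 0.049, and adjusted p = 0.48 with an estimated correlation). Its leading members were Acacb, the acetyl-CoA carboxylase that restrains mitochondrial fatty acid entry, at -0.35 ± 0.09, Me1 at -0.26 ± 0.10 (-0.13 without knockout replicate 3), Elovl1 at 0.12 ± 0.05 and Mlxipl at -0.16 ± 0.07. That call held in 6 of 16 alternatives and was lost without wild type replicate 1 or 3 or knockout replicate 1 or 2, and the mean ran from -0.036 without wild type replicate 1 to -0.16 without replicate 2. Cholesterol synthesis, at -0.07 ± 0.06 over 16 members, was not called (camera adjusted p = 0.25), with Sc5d at -0.25 ± 0.09, Fdft1 at -0.45 ± 0.21 and 0 members passing over the list alone or over all genes. It was called lower under array weights (camera adjusted p = 0.043) and without wild type replicate 2 (0.027), but its mean was -0.0226 with an upward test direction without wild type replicate 1 (camera adjusted p = 0.896) and -0.0351 without knockout replicate 2.

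Transcripts of the respiratory chain and of the cycle that feeds it were lower together, with list means between -0.16 and -0.15. Complex I genes fell by 0.16 ± 0.03 on average, with 22 of 34 lower when p was adjusted over the list alone and 0 over all genes. Ndufa8 differed by -0.29 ± 0.04, Ndufv1 by -0.24 ± 0.04, Ndufb8 by -0.24 ± 0.04 and Ndufs3 by -0.16 ± 0.03. Complex III, complex IV and cytochrome c genes fell by 0.16 ± 0.03, with 14 of 22 lower over the list alone and 0 over all genes. Cox5a, Cox8b (-0.26 ± 0.04), Uqcrc1 (-0.22 ± 0.04) and Uqcrfs1 (-0.31 ± 0.06) led them. ATP synthase genes fell by 0.16 ± 0.02, with 13 of 16 lower over the list alone and 0 over all genes, led by Atp5c1 at -0.24 ± 0.03 and Atp5a1 at -0.23 ± 0.04, then Atp5g1 at -0.17 ± 0.03 and Atp5j at -0.17 ± 0.03. Pyruvate dehydrogenase and tricarboxylic acid cycle genes fell by 0.15 ± 0.02, with 19 of 27 lower over the list alone and 0 over all genes. Its leading members were the succinate dehydrogenase subunits Sdhc and Sdhd (-0.23 ± 0.04), the succinyl-CoA ligase subunit Suclg1 (-0.28 ± 0.03) and the malate dehydrogenase Mdh1 (-0.29 ± 0.06).

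In all these mitochondrial lists the 3 knockout arrays lay below the 4 wild type arrays. Camera adjusted p was 2.6e-19 for complex I, 5.8e-13 for complexes III and IV, 3.9e-12 for ATP synthase and 1.9e-15 for the tricarboxylic acid cycle. With an estimated correlation the adjusted p was 0.079, 0.079, 0.062 and 0.035 in that order, so the last call alone held. Mitochondrial dynamics and mitophagy genes, which fuse, split and clear mitochondria, fell by 0.12 ± 0.02 over 14 members (camera adjusted p = 1.1e-05, and adjusted p = 0.062 with an estimated correlation). None of the 14 passed over the list alone or over all genes, and the leading ones were the fusion genes Mfn2 at -0.17 ± 0.05, Opa1 at -0.16 ± 0.05 and Mfn1 at -0.34 ± 0.12, and the mitophagy receptor Bcl2l13 at -0.13 ± 0.04. Regulators of mitochondrial biogenesis averaged -0.02 ± 0.05 over 19 members and were not called (camera adjusted p = 0.40), with 0 members passing over the list alone or over all genes and a sign that turned under array weights. Sirt3, a mitochondrial deacetylase, differed by -0.18 ± 0.05 and the nuclear receptor Esrra by -0.11 ± 0.04.

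Carbohydrate genes differed less evenly. Glycolysis genes fell by 0.13 ± 0.02 on average, with 2 of 13 lower over the list alone and 0 over all genes, while their median difference was -0.02. Ldhb, the lactate dehydrogenase form of oxidative fibres, differed by -0.68 ± 0.12 and Pfkm, muscle phosphofructokinase, by -0.15 ± 0.04. The lactate carriers Slc16a1 and Slc16a3, which are transporters and not glycolytic enzymes, differed by -0.36 ± 0.12 and -0.19 ± 0.08. The call (camera adjusted p = 0.027) was lost with an estimated correlation (adjusted p = 0.14) and without knockout replicate 1 or 3. Glycogen metabolism genes fell by 0.09 ± 0.03 over 16 members, with 0 passing over the list alone or over all genes (camera adjusted p = 0.027, and adjusted p = 0.17 with an estimated correlation). Ugp2, which makes UDP-glucose, differed by -0.33 ± 0.08, the branching enzyme Gbe1 by -0.34 ± 0.12, Epm2a by -0.24 ± 0.08 and Ppp1r3d by 0.15 ± 0.05. This call too was lost without wild type replicate 1 or knockout replicate 3. Glucose uptake and insulin signalling averaged -0.02 ± 0.07 over 19 members and was not called (camera adjusted p = 0.16), with a sign that turned after quantile normalization. It was called lower without knockout replicate 1 (camera adjusted p = 0.029) or 2 (0.046), but without replicate 3 the mean was 0.0469 with an upward test direction (camera adjusted p = 0.796). The insulin-responsive glucose transporter Slc2a4, at -0.24 ± 0.05, was the 1 member that fell over the list alone, 0 passed over all genes, and the insulin receptor Insr differed by -0.13 ± 0.05.

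Developmental and slow-fibre muscle genes were higher in knockout muscle, while fast-fibre genes were not called. Muscle regeneration genes rose by 0.44 ± 0.11 on average, with 7 of 13 higher and 1 lower over the list alone and 1 higher over all genes, which was Myh3. The perinatal myosin Myh8 differed by 0.35 ± 0.06, the embryonic light chain Myl4 by 0.67 ± 0.13 and the growth factor Igf2 by 0.80 ± 0.22, or 0.52 without knockout replicate 3. The member that fell, named after its value was seen, was the cadherin Cdh15 at -0.09 ± 0.03. The call held with the preset correlation (camera adjusted p = 6.5e-09) and with the estimated one (adjusted p = 0.035). Slow fibre genes rose by 0.41 ± 0.12, with 9 of 18 higher and 2 lower over the list alone and 0 over all genes (camera adjusted p = 4.1e-07, and adjusted p = 0.14 with an estimated correlation). Slow troponin I, Tnni1, differed by 1.00 ± 0.17, the slow calcium pump Atp2a2 by 0.76 ± 0.15, the light chain Myl6b by 0.30 ± 0.06 and sarcolipin, Sln, by 0.44 ± 0.10. Those that fell, named after their values were seen, were myoglobin (Mb) at -0.16 ± 0.04 and phospholamban (Pln) at -0.25 ± 0.09. Fast fibre genes averaged 0.02 ± 0.01 over 19 members and were not called (camera adjusted p = 0.16), with 0 passing over the list alone or over all genes, Mylk2 at -0.25 ± 0.09 and Casq1 at 0.08 ± 0.03. They were called higher without knockout replicate 3 (camera adjusted p = 0.030), and their mean ran from 0.0111 to 0.0241 when 1 array was left out.

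Neuromuscular junction and denervation genes rose by 0.24 ± 0.06 on average over 17 members, with a median of 0.07. Over the list alone 3 rose and 1 fell, and 0 passed over all genes. Ncam1, an adhesion molecule that spreads along denervated fibres, differed by 1.01 ± 0.14 and the transcription factor Runx1, induced by denervation, by 1.37 ± 0.29, from 8.33 to 9.70. The acetylcholine receptor subunit Chrna1 differed by 0.24 ± 0.06 and rapsyn, Rapsn, which clusters these receptors, by -0.24 ± 0.06. The call (camera adjusted p = 3.4e-04) was lost with the estimated correlation (adjusted p = 0.14). Macrophage markers were 0.51 higher in the same 3 arrays as these regeneration, slow fibre and junction genes.

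Blood vessel transcripts were lower in knockout muscle. Endothelial markers fell by 0.32 ± 0.06 on average, with 14 of 14 below wild type, 9 of them lower over the list alone and 0 over all genes, and with no overlap between the genotypes. The phosphatase Ptprb differed by -0.38 ± 0.05, the junction cadherin Cdh5 by -0.32 ± 0.06, endomucin (Emcn) by -0.59 ± 0.11 and the receptor Tie1 by -0.37 ± 0.07. Angiogenesis genes, of which 2 (Kdr and Tek) are also among the endothelial markers, fell by 0.14 ± 0.06 over 16 members, with 3 lower over the list alone and 0 over all genes. These were the growth factor Vegfb at -0.48 ± 0.06, the hypoxia-responsive transcription factor Epas1 at -0.37 ± 0.07 and the receptor Kdr at -0.67 ± 0.17, followed by the receptor Flt1 at -0.40 ± 0.14, or -0.25 without knockout replicate 3. Smooth muscle and pericyte markers averaged -0.09 ± 0.04 over 11 members, with 4 lower and 1 higher over the list alone and 0 over all genes. Notch3 (-0.29 ± 0.05), Kcnj8 (-0.28 ± 0.05) and Rgs5 (-0.41 ± 0.09) were lower, as was Myh11 (-0.36 ± 0.11), named after its value was seen, and Mustn1 (0.89 ± 0.13), which muscle fibres also express, was higher. Camera adjusted p was 3.2e-10 for endothelial, 0.0038 for angiogenesis and 0.011 for pericyte genes, and with an estimated correlation the adjusted p was 0.12, 0.079 and 0.33. The pericyte call was also lost without wild type replicate 1.

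Macrophage transcripts were higher in every knockout array than in any wild type array. The 15 macrophage and monocyte markers rose by 0.51 ± 0.07 on average, all 15 lay above wild type, and 11 rose over the list alone against 1, Lyz2, over all genes. The complement genes C1qb and C1qc differed by 0.80 ± 0.10 and 0.61 ± 0.09, and Ly86, a partner of a toll-like receptor, by 0.72 ± 0.11. The camera adjusted p was 1.6e-18, and the adjusted p was 0.058 with an estimated correlation. Fibroblast markers rose by 0.25 ± 0.11 over 11 members, with 2 higher over the list alone and 0 over all genes (camera adjusted p = 9.5e-05, and adjusted p = 0.37 with an estimated correlation). These were the matrix protein Dpt at 0.42 ± 0.08 and the growth factor receptor Pdgfra at 0.53 ± 0.11, while Dpp4 differed by -0.33 ± 0.12 and Mfap5 by 0.52 ± 0.20. Extracellular matrix genes averaged 0.27 ± 0.17 above wild type over 19 members, with 0 passing over the list alone or over all genes. Knockout replicate 1 read 9.68 for that list, within the wild type range of 9.63 to 9.85, while replicates 2 and 3 read 10.14 and 10.20. Fibronectin (Fn1) differed by 0.55 ± 0.16, periostin (Postn) by 1.00 ± 0.30, Mmp2 by 0.58 ± 0.19 and Tgfb1 by 0.26 ± 0.09 (camera adjusted p = 4.8e-05, and adjusted p = 0.45 with an estimated correlation). Without knockout replicate 3, Mmp2 was 0.35 and Tgfb1 0.17. The matrix mean was 0.43 without knockout replicate 1, 0.20 without replicate 2 and 0.17 without replicate 3, and its call was also lost with fry (adjusted p = 0.29), as was the fibroblast call.

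**Figure D4:**
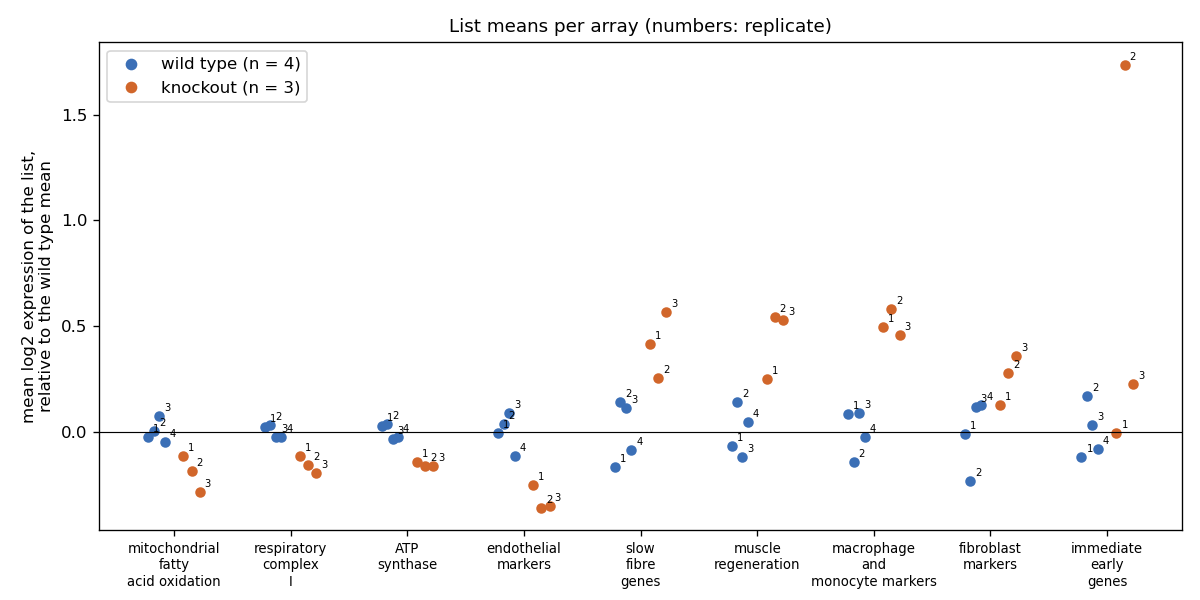
Mean log2 expression of 9 gene lists in each array, relative to the wild type mean of that list, with points numbered by replicate (wild type n = 4, knockout n = 3). Fatty acid oxidation, complex I, ATP synthase, endothelial, slow fibre, regeneration, macrophage and fibroblast lists do not overlap between the genotypes, while the immediate early genes stand out in knockout replicate 2.

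The means of the immediate early and stress lists were high in 1 knockout array. The 22 immediate early genes averaged 10.37 in knockout replicate 2, 8.62 and 8.86 in the other knockout arrays and 8.51 to 8.80 in wild type. Their mean difference was 0.65 ± 0.55, with 0 passing over the list alone or over all genes. Atf3, a stress-induced transcription factor, differed by 2.09 ± 0.61, with every knockout array above every wild type array. Fosl1 differed by 0.33 ± 0.12, Myc by 0.87 ± 0.45 and Fosb by 0.94 ± 0.49. Without knockout replicate 2 the last 3 were 0.18, 0.25 and 0.26. The call (camera adjusted p = 3.8e-06) was lost with an estimated correlation (adjusted p = 0.48) and without knockout replicate 2, where the mean was 0.11, against 0.98 without knockout replicate 1. Heat shock and unfolded protein response genes averaged 0.23 ± 0.22 above wild type over 18 members, with 1 higher over the list alone and 0 over all genes. The 1 was Hspb7 at 0.68 ± 0.13, again with every knockout array above every wild type array. Hspb1 differed by 0.68 ± 0.28, Hspa1a by 1.15 ± 0.61 (0.34 without knockout replicate 2) and Herpud1 by -0.15 ± 0.05 (-0.10 without knockout replicate 3). That call (camera adjusted p = 0.030, and adjusted p = 0.48 with an estimated correlation) was lost without knockout replicate 2, where the mean was 0.03, and without wild type replicate 1 or 4 or knockout replicate 1. The heat shock mean was 0.37 without knockout replicate 3. For antioxidant genes the mean, 0.07 ± 0.10, and the median, -0.03, differed in sign over 21 members, and the list was not called (camera adjusted p = 0.32). The mitochondrial Sod2 and Prdx3 (-0.24 ± 0.05) fell over the list alone, and 0 passed over all genes.

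The remaining lists moved little. Ribosomal protein genes averaged 0.04 ± 0.04 above wild type over 19 members, with Rpl19 at 0.12 ± 0.04, Rpl7 at 0.11 ± 0.05, Rpl10a at 0.09 ± 0.04 and Rpl6 at 0.07 ± 0.03, and 0 passing over the list alone or over all genes. The call (camera adjusted p = 0.0048) was lost with an estimated correlation (adjusted p = 0.48) and without knockout replicate 1 or 2. The mean was 0.0083 without knockout replicate 1 and 0.075 without replicate 3. Branched-chain amino acid breakdown averaged -0.06 ± 0.06 over 18 members, with 0 passing over the list alone or over all genes (camera adjusted p = 0.027, and adjusted p = 0.48 with an estimated correlation). Bckdk, the kinase that restrains this pathway, differed by -0.19 ± 0.05, Bckdha by -0.23 ± 0.08, Acad8 by -0.12 ± 0.04 and Hibadh by -0.11 ± 0.04. That call held in 8 of 16 alternatives and was lost without wild type replicate 1 or knockout replicate 2 or 3. Its mean was -0.035 without wild type replicate 1 or knockout replicate 3 and -0.11 without knockout replicate 1. Nucleotide and creatine metabolism averaged -0.01 ± 0.03 over 21 members and was not called (camera adjusted p = 0.35). Over the list alone 3 members rose and 3 fell, and 0 passed over all genes. Gamt, which completes creatine synthesis, differed by 0.83 ± 0.12 and the mitochondrial creatine kinase Ckmt2 by -0.49 ± 0.07. Named after their values were seen, Gatm (0.51 ± 0.12) and Ampd3 (0.45 ± 0.08) were the remaining higher members, and Nt5c1a (-0.46 ± 0.12) and Adsl (-0.13 ± 0.04) the remaining lower ones.

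AMPK upstream and substrate genes averaged -0.06 ± 0.05 over 21 members, with Acacb and Camkk2 (0.16 ± 0.05) leading, and AMPK-related kinases 0.04 ± 0.04 over 13 members, with Snrk at -0.26 ± 0.10 and Nuak1 at 0.19 ± 0.11. Autophagy and lysosome genes averaged 0.01 ± 0.03 over 26 members, with Ctsd at -0.23 ± 0.06 and Lamp2 at 0.27 ± 0.07. Atrophy and proteasome genes averaged -0.03 ± 0.12 over 16 members, with Foxo4 at -0.31 ± 0.08 and Mstn at -0.69 ± 0.38. Circadian clock genes averaged -0.02 ± 0.09 over 18 members, with Cry1 at -0.16 ± 0.07, Wee1 at 0.27 ± 0.15 and a camera direction opposite to the mean. These 5 lists were not called, with camera adjusted p of 0.096, 0.87, 0.69, 0.80 and 0.91 in the order given, and 0 of their members passed over the list alone or over all genes. AMPK upstream and substrate genes were called lower with the replicate block (camera adjusted p = 0.036) and without wild type replicate 2 (0.031), wild type replicate 4 (0.0255) or knockout replicate 2 (0.0105). Their mean ran from -0.0855 to -0.0128 when 1 array was left out, nearest 0 without knockout replicate 3 (camera adjusted p = 0.796), and was -0.025 under array weights (camera adjusted p = 0.476). Atrophy genes were called lower without knockout replicate 2 (mean -0.12, camera adjusted p = 0.0385), but without knockout replicate 3 their mean was 0.0676 with an upward test direction (camera adjusted p = 0.117). Mstn was -0.20 without knockout replicate 3 and -1.055 without replicate 1. The AMPK-related kinase mean ran from 0.0099 to 0.061 when 1 array was left out, with a downward test direction without wild type replicate 1 or 4 or knockout replicate 2. Snrk was -0.15 without knockout replicate 2, and Nuak1 0.11 without wild type replicate 2 and 0.10 without knockout replicate 1. Cry1 was -0.07 without knockout replicate 3, and Wee1 0.16 without wild type replicate 2 or knockout replicate 2. The autophagy, atrophy and circadian means turned sign under other scalings or array weights.

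Markers of further cell types were not called. Tendon markers averaged -0.10 ± 0.07 over 9 members (Mkx -0.23 ± 0.08), adipocyte markers -0.02 ± 0.07 over 10 members (Car3 0.51 ± 0.14) and lymphocyte markers 0.03 ± 0.03 over 11 members (Ptprc 0.25 ± 0.07). Neutrophil markers averaged 0.02 ± 0.03 over 9 members (Ngp 0.07 ± 0.05), Schwann cell markers -0.02 ± 0.05 over 8 members (Ncmap -0.18 ± 0.06) and skin markers -0.14 ± 0.17 over 10 members (Krt14 -0.17 ± 0.15). Satellite cell markers averaged 0.02 ± 0.05 over 10 members, and Notch3, shared with the pericyte list, was the 1 member of these lists to fall over the list alone. Camera adjusted p for tendon, adipocyte, lymphocyte, neutrophil, Schwann, skin and satellite lists was 0.23, 0.90, 0.35, 0.35, 0.59, 0.38 and 0.90. Tendon markers were called lower without wild type replicate 2 (camera adjusted p = 0.024) or knockout replicate 2 (0.029), and their mean ran from -0.146 to -0.0502 when 1 array was left out, nearest 0 without wild type replicate 3 (camera adjusted p = 0.673). Mkx was -0.15 without knockout replicate 2, and without wild type replicate 2 Krt14 was -0.03 and Ngp 0.04, the latter also without knockout replicate 3. When 1 array was left out the lymphocyte mean ran from 0.0033 to 0.045 and the neutrophil mean from 0.013 to 0.048. The satellite test pointed down although its mean and median were above 0. Red blood cell markers, with 3 measured members and no test, averaged 7.75 ± 0.15 (SD, n = 4) in wild type and 7.72 ± 0.49 (SD, n = 3) in knockout, with Epb42 at 0.09 ± 0.06, or 0.02 without knockout replicate 1. The 4 sex-linked genes differed by -0.01 ± 0.03, and Eif2s3y on the Y chromosome by -0.09 ± 0.10 (-0.16 without wild type replicate 2, -0.03 without wild type replicate 3 and -0.02 without knockout replicate 3). The remaining 3 were named after their values were seen. Xist read between 5.45 and 5.75 in all 7 arrays, and the Y-linked Uty and Kdm5d between 8.85 and 9.17 and between 8.11 and 8.38. Xist lay below the lower quartile of every array (6.479 to 6.577), while the Y-linked genes lay above every array median (7.501 to 7.584). This pattern points to male mice in both groups and argues against a difference in sex between the genotypes.

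Genes beside the targeted loci were read because a knockout can carry neighbouring variants of its founder strain. Over all tested genes, 10.6% had an unadjusted p under 0.05 in limma. Of 31 measured neighbours of Prkaa1, 0 had an adjusted p under 0.05 in limma and 7 had an unadjusted p under 0.05, a larger share. Among these neighbours the smallest p belonged to Fyb, an adaptor of blood cells, at 0.30 ± 0.08 (adjusted p = 0.26). Of 40 measured neighbours of Prkaa2, 0 had an adjusted p under 0.05 in limma and 4 had an unadjusted p under 0.05, led by the mitochondrial ribosomal gene Mrpl37 at -0.17 ± 0.05 (adjusted p = 0.33).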

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

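The tests of a lower share of muscle fibre RNA, of knockout replicate 2 alone, of a shift from slow to fast fibres and of residual blood were chosen after the results were seen, and the remaining tests before. Within the 4 wild type arrays, 1 array stood far from the other 3 for 18 of 186 genes and lists tested, where chance gives about 1 in 20. Wild type replicate 2 was lowest for Prkaa2 at 12.03 (others 12.28 to 12.31), Nuak1 at 9.38, Elovl1 at 8.93, Mylk2 at 12.26, Kcnj8 at 9.70, C1qc at 8.54, Ngp at 6.02 and the AMPK subunit list at 10.29. It was highest for Atp5a1 at 13.14, Atf3 at 10.02 (others 8.41 to 8.64), Krt14 at 7.68 and the skin marker list at 7.66 (others 6.95 to 7.05). Wild type replicate 3 was lowest for Prkab2 at 11.23 and Myl4 at 10.20, and highest for Prkag1 at 11.01 and the angiogenesis list at 9.25. Wild type replicate 4 was highest for Hibadh at 12.01 and Rpl7 at 11.30. No explanation for these arrays was tested.

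The real grouping gave 5 changed genes and the highest of the other splits gave 0, so 1 of the 35 splits, the real one, gave as many. That share, 2.86%, is the smallest that 35 splits can give, so it argues against chance for that count without excluding it. The count itself was 0 without wild type replicate 1, 3 or 4. For pathway lists the real value was 21 and the highest other was 23, for the split that set wild type replicates 1, 3 and 4 apart. That split moves only wild type replicate 2 to the knockout side, so it shares most of the genotype contrast. A split that mixed the genotypes more, wild type replicates 1 and 3 with knockout replicate 1, gave 19. In all, 2 of the 35 splits gave 21 or more, so chance cannot be excluded for calls with the preset correlation. With an estimated correlation the real value was 2 and the highest other 0. For cell type lists the real value was 4 and the highest other 5, and 9 of the 35 splits gave as many, so chance cannot be excluded there either.

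Strain variants carried along with the targeted loci may shift the genes around Prkaa1 and Prkaa2. Of 184 genes within 10 Mb of either, 0 had an adjusted p under 0.05, against 5 of 19753 elsewhere, a count too small to decide although the odds ratio of 0 is below 1. At an unadjusted p under 0.05 the odds ratio was 1.27 (95% interval 0.786 to 1.96, one-sided Fisher's exact test p = 0.169). Neither test decides, because both intervals reach above and below 1, so linked variants and the targeted deletions cannot be told apart for these genes. Both tests pooled the loci, so an excess at Prkaa1 alone was not tested. Nnt, chosen after its values were seen, differed by -0.55 ± 0.08 (limma adjusted p = 0.095), and a deletion in this gene separates C57BL/6J from other strains, so unlinked strain differences stay open as well.

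The mitochondrial lists were lower in the knockout. A brightness-dependent array effect was argued against by the median difference of their 123 genes, -0.17, below all 10000 sets matched on signal, whose lowest was -0.07. The endothelial list moved by -0.32 while the macrophage list moved by 0.51, so the other cell types did not rise alike. That alone does not decide on a lower share of muscle fibre RNA, since more macrophage RNA would lower the shares of fibre and endothelial RNA together. A lower fibre share would lower fast fibre genes too, but that list differed by 0.02 ± 0.01 over 19 members. Of these, 12 lay above and 7 below wild type. This argues against a lower fibre share without excluding it, and glycolysis genes fell by 0.13 on average with a median of -0.02. Without knockout replicate 2 the mean of the mitochondrial genes was -0.16, which argues against that array alone. The slow fibre list differed by 0.41, which argues against a shift from slow to fast fibres only as far as its members mark fibre type. Of its 18 members, 9 rose and 2 fell over the list alone. Ldhb, the form of oxidative fibres, differed by -0.68 ± 0.12, and muscle regeneration genes rose by 0.44 ± 0.11 in the same arrays. Whether the slow fibre rise came with regeneration or with fibre type was not tested. The slow fibre list does not measure a shift among the types of fast fibre, which was not tested. Lower mitochondrial transcripts may follow the genotype, as a hypothesis. It leaves a lower share of muscle fibre RNA not excluded, and the types of fast fibre, strain background and activity of the mice untested.

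The macrophage list was higher in the knockout by 0.51 ± 0.07. Without knockout replicate 2 the difference was 0.48, which argues against that array as the whole cause. Residual blood stays open, since the red blood cell list differed by -0.032 ± 0.29 with 3 measured genes, and 2 standard errors reach the macrophage shift. That spread comes from knockout replicate 1 at 8.27, while replicates 2 and 3, at 7.335 and 7.544, lay below all wild type arrays (7.65 to 7.97), which runs against blood in those arrays. More macrophages, or more of these transcripts per cell, may each give this pattern, which these arrays do not separate.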

How the results depend on the processing

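With the replicate block, which has no pairing behind it, genes changed numbered 0 (0 higher, 0 lower; limma, 1653 at an unadjusted p under 0.05). Quantile normalization gave 2 genes lower, 9 pathway lists lower, glucose uptake 0.0037 and nucleotide and creatine metabolism 0.0046, and median centring gave autophagy -0.00074. With probe sets above the median only, 8 pathway lists and 1 cell type list were lower. Array weights reversed Prkab1 to -0.042, PPAR targets to 0.019, glucose uptake to 0.028, mitochondrial biogenesis to 0.016, atrophy to 0.050 and circadian clock to 0.038. All probe sets left 0 genes lower, with 4 higher and 2675 at an unadjusted p under 0.05 in limma. At an adjusted p under 0.10 there were 72 genes (48 higher, 24 lower). An estimated correlation left 2 pathway lists (1 higher, 1 lower) and 0 cell type lists (0 higher, 0 lower), and fry 13 (3 higher) and 2 (1 higher, 1 lower). The mean of all probe sets of a gene gave nucleotide metabolism 0.0016. Leaving out 1 array at a time gave 0 to 14 genes (0 to 8 higher, 0 to 6 lower), with 1581, 1505 and 1608 at an unadjusted p under 0.05 in limma where wild type replicate 1, 3 or 4 was left out and 0 passed. It gave 4 to 8 pathway lists higher and 9 to 15 lower, and 1 to 3 cell type lists lower. Over those fits Prkab1 ran from -0.024 to 0.064, nucleotide metabolism from -0.031 to 0.0069, circadian clock from -0.079 to 0.043, autophagy from -0.0080 to 0.025, adipocyte from -0.085 to 0.020, skin from -0.21 to 0.026, atrophy from -0.12 to 0.068, Schwann from -0.074 to 0.012, antioxidant from -0.017 to 0.14, satellite from -0.018 to 0.055, glucose uptake from -0.062 to 0.047 and mitochondrial biogenesis from -0.057 to 0.028. Such fits moved 26 of 140 named genes and 24 of 44 lists by over 1.5 times. The cause was not tested. The muscle regeneration and tricarboxylic acid cycle lists were called in 16 of 16 alternatives. Prkaa1 ran from -0.59 to -0.40 and Prkaa2 from -0.28 to -0.19 when 1 array was left out. Signal near background limits small differences of dim genes.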

Other observations

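All genes here except Hspa1a, which the rule had named, were chosen after their values were seen, and none had a limma adjusted p under 0.05. The 15 probe sets of the cadherin Fat3 were all lower in the knockout without overlap, with log2 differences from -0.216 to -0.998 and a median of -0.35. Fam171b differed by 1.44 ± 0.20, Ttc9 by 1.41 ± 0.17, Eda2r by 1.17 ± 0.14, Sntb1 by 1.07 ± 0.16 and Cpne2 by 0.95 ± 0.13. Antigen presentation genes differed by 1.03 ± 0.14 for H2-Aa, 0.90 ± 0.11 for Cd74, 0.86 ± 0.11 for H2-Ab1 and 0.61 ± 0.13 for H2-Eb1. Further myeloid genes, Mpeg1 (0.73), C3ar1 (0.75), Fcer1g (0.64) and Gpnmb (0.60), were higher without overlap, while the neutrophil genes S100a8 (0.08) and S100a9 (0.05) overlapped between the genotypes. In knockout replicate 2, Socs3 read 12.37 against 8.27 to 8.73 in the other arrays, Mt1 12.64 against 9.44 to 9.96 and Hspa1a 12.10 against 9.04 to 9.92.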
